A study of Homo sapiens with 6 samples.

How the data were processed

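RNA immunoprecipitation followed by sequencing (RIP-seq) of the RNA helicase DDX5 was performed, per the labels' protocols, on nuclear extracts of RH30, an established alveolar rhabdomyosarcoma cell line that carries the PAX3-FOXO1 fusion gene. The series held 6 samples, 3 immunoprecipitates with a DDX5 antibody and 3 INPUT samples without one. The labels call them biological replicates. Libraries were made with an unstranded RNA-seq kit that copies total RNA, per the labels' protocols, so sense and antisense transcripts could not be told apart. One peak list for each DDX5 immunoprecipitate was analysed. Files of the INPUT samples were not analysed here.

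Per the submitters' processing notes, the tools bcl2fastq 2.20, FastQC 0.11.8, cutadapt 1.11, STAR 2.6.1d, SAMtools 1.10 and MACS2 2.2.7.1 and the build GRCh38/hg38 were used. The notes give neither the parameters nor which library served as the control of the peak calls. The layout of the deposited lists, with 1 list per sample and several summits in some intervals, is that of a peak caller run on each sample. The fold enrichment of each peak over the caller's background is a ratio made by the authors. The deposited p-value and q-value of each summit are on the −log10 scale. The deposited score is a number derived from the q-value and was not used further. The largest q-value averaged 0.0499 over the 3 lists. These values belong to single peaks and served only to describe, rank or filter peaks within a list. The sequencing depth behind the lists is unknown, so no interval that needs it is given. The number of peaks in a list can depend on that depth.

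Chromosome names were matched to the reference, and every peak on the main chromosomes ended within the length of its GRCh38 chromosome. Peaks on chromosomes 1 to 22, X, Y and the mitochondrial genome were kept. Summits that shared an interval were counted as 1 peak, represented by the summit with the highest −log10 q. Genes came from GENCODE version 44, without the copies of the pseudoautosomal genes on Y. A summit was given to the gene whose exon held it if exactly 1 did, otherwise to the gene whose body held it if exactly 1 did, and otherwise to no gene. The feature at a summit was taken in the order coding sequence, 5' UTR, 3' UTR, non-coding exon, intron and intergenic.

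Peaks of the 3 lists that shared at least 1 bp were merged into regions. Regions found in all lists were set against 100 shuffles that moved each gene-assigned peak to a random place in its own gene, with a one-sided p whose smallest possible value is 0.0099. Feature shares were set against the same kind of shuffle, and the 3 log2 ratios were tested with an exact two-sided sign-flip permutation test, which cannot give a p below 0.25 with 3 lists. A total of 16 gene lists with 715 entries were fixed before the data were examined, and 3 entries had no match in the annotation. Each list was tested with a two-sided Fisher's exact test for genes with a peak in every list, against genes with a peak in at least 1 list, with Benjamini-Hochberg adjustment over the 16 lists and a threshold of 0.05. Odds ratios have 95% normal-approximation intervals on the log scale, with 0.5 added to each cell where a cell was 0. GC content and the share of windows with 4 runs of at least 3 G, spaced by 1 to 7 bases, were taken within 50 bases on each side of the summit. They were compared with 100 random draws from the same gene and feature class. Rank correlations between lists were computed across genes, which are not independent replicates, and carry no p.

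The genes named in the text were chosen by a rule fixed before the data were examined. It took DDX5, PAX3, FOXO1, EHMT1 and EHMT2, the 15 protein-coding and the 10 other genes with a peak in every list that ranked highest by the mean percentile of their best −log10 q, and up to 4 such members of each gene list. Genes of chromosome Y and XIST were not named. Not every gene the rule took is described. Genes named outside this rule are marked as such. The best peak of a gene is the one with the highest −log10 q in a list, and its fold enrichment is the value given for a gene.

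Alternatives covered a stricter q, a minimum fold, equal list lengths, each replicate left out, other definitions of overlap, exon-only assignment, genes in 2 or more lists, random lists matched on gene length and type, wider sequence windows and, for the number of peaks, all contigs. The matched gene length was the span from gene start to gene end, introns included. Added after the data were seen was leaving out peaks whose pair of fold and p was shared by 10 or more peaks of the list, and giving a summit in several genes to the only protein-coding gene among them. The computations were tested on simulated data. For the overlap of replicates, 5 simulations on 82589 peaks with no shared place gave an observed over shuffled ratio of 0.977 ± 0.0603 (SD), and all of 1000 planted shared places were found. For the gene lists, a list given an odds ratio of 4 among 10205 genes was estimated at 4.03 and called in 94% of simulations, while 0.4% of unchanged lists were called. All unchanged genes had the same probability there, so false calls from gene length, type or abundance were not covered. The changed list was that of the cell cycle, with 48 genes with a peak, so the 94% does not hold for shorter lists. For the features of peaks, 67.8% of the simulated peaks were placed in exons and 68.1% were found there. For the sequence under peaks, control places taken as summits in 2000 regions differed in GC by 0.00879 ± 0.158 points (SD). Merging gave the same 60437 regions as bedtools. The work used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6, pysam 0.24.0 and matplotlib 3.10.9.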

Results

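DDX5, a DEAD-box RNA helicase, was immunoprecipitated from nuclear extracts of RH30 cells, and the RNA that came with it was sequenced. RH30 is a fusion-positive alveolar rhabdomyosarcoma line whose driver joins the DNA-binding part of PAX3 to the transactivating part of FOXO1. The question addressed was which RNAs DDX5 binds in these nuclei. The deposited lists held 23715, 23651 and 45832 peaks on the main chromosomes in replicates 1, 2 and 3, a mean of 31066 ± 12788 (SD, n = 3). The median peak was 185 ± 10.3 bp wide (SD, n = 3) and had a fold enrichment of 2.93 ± 0.274 (SD, n = 3) over the authors' background. The highest fold enrichments were 18.04, 21.5 and 19.3. The depth of the libraries is unknown. INPUT levels were not analysed here, so no RNA abundance stands beside the peaks. In each list, 53.7%, 61.0% and 68.0% of peaks carried a pair of fold and p shared by 10 or more peaks of that list. The folds of the 10 commonest pairs lay on equal steps of 0.180, 0.160 and 0.171, so many peaks of a list share a background value. The control of the peak calls is not stated either, so a fold enrichment here cannot be read as enrichment over INPUT and can carry the abundance of the RNA.

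The peaks lay mostly in the exons of protein-coding genes. Coding sequence held 38.4% ± 11.2 of the summits (SD, n = 3), with 37.6%, 27.5% and 49.9% in replicates 1, 2 and 3. The 3' UTRs held 31.9% ± 8.99 (SD, n = 3), with 41.9%, 29.2% and 24.6%. Introns held 20.3% ± 10.97 (SD, n = 3), with 11.9%, 32.7% and 16.3% in replicates 1, 2 and 3. Intergenic sequence held 4.12% ± 1.16, non-coding exons 3.76% ± 0.267 and 5' UTRs 1.57% ± 0.45 (SD, n = 3). Each of these small shares was higher by more than 1 SD with fold enrichments of at least 4, as given with the alternatives below. Any exon held 75.6% ± 11.97 (SD, n = 3). Among peaks assigned to a gene, the share in coding sequence was 6.64 ± 1.54 times that of peaks shuffled within the same genes, and the share in 3' UTRs was 5.31 ± 0.99 times (SD, n = 3). Introns were at 0.247 ± 0.134 times the shuffled share (SD, n = 3). Non-coding exons were at 0.668 ± 0.0737 times and 5' UTRs at 1.22 ± 0.355 times (SD, n = 3). Coding sequence, 3' UTRs, introns and non-coding exons each departed in the same direction in 3 of 3 lists, with an exact two-sided sign-flip p of 0.25, the smallest that 3 lists can give. For 5' UTRs that p was 0.5. The shuffle does not account for exons being more abundant than introns in RNA.

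**Figure D1:**
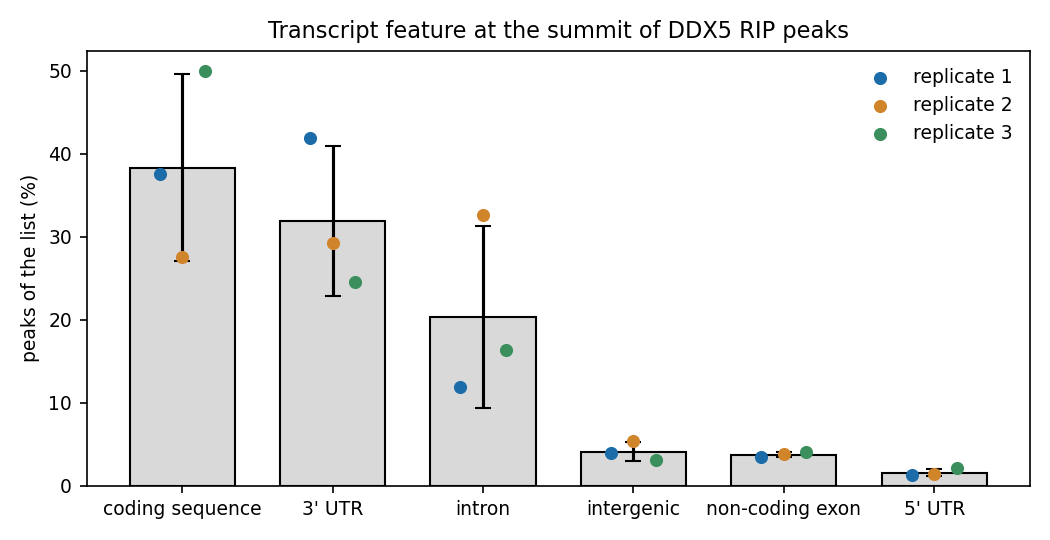
Share of the peaks of each list (y axis, percent) by the transcript feature at the summit (x axis). Bars are means and whiskers SDs over the 3 DDX5 immunoprecipitates, and points are single replicates. Coding sequence (38.4%) and 3' UTRs (31.9%) lead in the mean. In replicate 1 3' UTRs lead, at 41.9%, and in replicate 2 introns lead, at 32.7%, the highest intronic share of the replicates.

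The replicates shared peaks in the same places within genes. Merged across the 3 lists, the peaks formed 60437 regions, of which 8190 (13.6%) were found in all 3 lists, 12808 in 2 and 39439 in 1. Of the peaks of replicates 1, 2 and 3, 37.7%, 37.1% and 18.4% touched a peak of both other lists. Among gene-assigned peaks, 7333 regions lay in all 3 lists, against 386.4 ± 15.5 (SD over 100 shuffles) when peaks were moved within their genes, a ratio of 18.98 (one-sided permutation of positions, p = 0.0099, the smallest that 100 shuffles can give). With exonic peaks moved only within the exons of their gene the ratio was 4.77, from 6583 observed against 1379 ± 26.7 shuffled (permutation of positions, p = 0.0099). Both shuffles spread peaks evenly, so they do not account for uneven read coverage along transcripts that libraries can share. No INPUT list was analysed, so the ratios do not show that the shared places are DDX5 sites. Of the regions found in all lists, 44.2% had their summit in a 3' UTR, 44.03% in coding sequence and 4.99% in an intron. The number of shared regions fell to 490 with fold enrichments of at least 4 to 3446 with q under 1e-05, to 4285 with reciprocal overlap of 50% and to 5041 with summits within 100 bp.

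**Figure D2:**
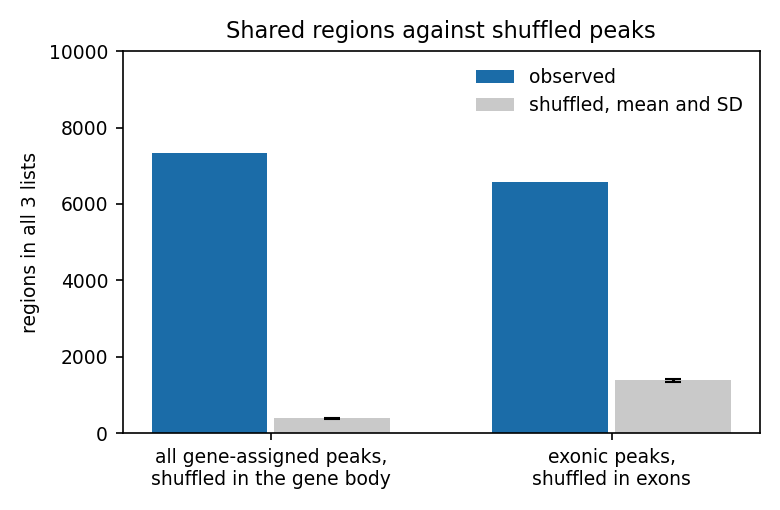
Number of merged regions found in all 3 lists (y axis), observed and after shuffling, for all gene-assigned peaks moved in their gene body and for exonic peaks moved within exons (x axis). Grey bars are means over 100 shuffles with SD whiskers. The observed numbers, 7333 and 6583, exceed the shuffled means of 386.4 and 1379.

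In all, 10205 genes had a peak in at least 1 list and 4416 (43.3%) had one in every list. These 4416 were 4279 protein-coding genes, 21.3% of those annotated, 103 long non-coding RNA genes and 34 others. Replicates 1, 2 and 3 held 6360, 6661 and 8705 genes. Across genes, the best fold enrichment correlated between lists with Spearman's rho of 0.32 for replicates 1 and 2, 0.44 for replicates 1 and 3 and 0.33 for replicates 2 and 3, over 4658, 5698 and 5581 genes. With fold enrichments of at least 4, 686 genes had a peak in every list, with q under 1e-05 2550 did, and 2184 did without the peaks on shared pairs of fold and p, an alternative chosen after the data were seen. The mean rank correlation was also lower with fold enrichments of at least 4, as given with the alternatives below.

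Among protein-coding genes with a peak in every list, ZNF805, a zinc finger gene on chromosome 19 (57240632 to 57262728, GRCh38), ranked first, with a fold enrichment of 11.8 ± 3.93 (SD, n = 3) at its best peaks. Those peaks lay in coding sequence in replicates 1 and 3 and in the 3' UTR in replicate 2. A 3' UTR region found in all lists spanned 57259680 to 57262704. FOXP4, a forkhead transcription factor gene, reached 10.7 ± 0.638 (SD, n = 3), in a 3' UTR region on chromosome 6 from 41599402 to 41600606. MBD6, a methyl-CpG-binding domain gene, reached 10.9 ± 6.17 (SD, n = 3), with 4.79, 17.1 and 10.7 in replicates 1, 2 and 3, in coding sequence on chromosome 12 from 57524646 to 57527145. NFIC reached 8.51 ± 0.741 (SD, n = 3). The stress kinase kinase gene MAP2K7 was at 9.07 ± 2.18, and the kinase genes HIPK3 and HIPK2 were at 7.78 ± 2.59 and 4.97 ± 0.466 (SD, n = 3). SOCS3, an inhibitor of cytokine signalling, was at 11.9 ± 2.98, and the thyroid hormone receptor gene THRA at 11.4 ± 1.62 (SD, n = 3). ATN1, ADGRA3, NECTIN1, TP53INP2 and KIAA1522 were also among the 15, between 6.83 ± 0.835 for TP53INP2 and 11.6 ± 3.97 for ADGRA3 (SD, n = 3). The ADGRA3 region was intronic and 12060 bp long, on chromosome 4 from 22372289 to 22384348.

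Among the 10 highest-ranked other genes, SNHG14, the long transcript of the Prader-Willi and Angelman region that hosts small nucleolar RNAs, held 35, 21 and 39 peaks in replicates 1, 2 and 3, with a best fold enrichment of 11.8 ± 3.91 (SD, n = 3). A further 3, 12 and 3 summits in SNHG14 overlapped a second gene record and were left out, which lowers the count of replicate 2 most. ENSG00000280614 was at 13.8 ± 4.47 (SD, n = 3), and this record lies on chromosome 21 from 8393419 to 8394341, within a copy of the 18S ribosomal RNA gene, RNA18SN3 (8392666 to 8394534). NUTM2B-AS1 was at 11.5 ± 4.41, LINC00639 at 6.27 ± 2.06 and ENSG00000286924 at 12.5 ± 6.07 (SD, n = 3). ENSG00000289950 was at 6.01 ± 0.546, ENSG00000268205 at 6.44 ± 3.79 and ENSG00000272405 at 4.85 ± 1.70 (SD, n = 3). BEND3P1, at 13.5 ± 6.06, and MTX1P1, at 5.08 ± 1.44 (SD, n = 3), are pseudogenes whose reads can be shared with their parent genes. The best peaks of NUTM2B-AS1, LINC00639, ENSG00000286924, ENSG00000289950 and MTX1P1 were intronic in every list.

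The transcripts of DDX5 itself and of the fusion partners were in every list, but none of them was with q under 1e-05. The best −log10 q of DDX5 was 4.50, 1.42 and 13.2 in replicates 1, 2 and 3. In replicate 1 the best −log10 q was 3.98 for PAX3 and 3.96 for FOXO1. DDX5 (chromosome 17, 64498254 to 64508199) held 2, 1 and 4 peaks in replicates 1, 2 and 3, with a best fold enrichment of 1.84 ± 0.404 (SD, n = 3), in sequence annotated as 5' UTR in each list. The best DDX5 peaks of replicates 1 and 3 both began at 64506048. That of replicate 2 spanned 64504837 to 64504999 and did not overlap them. Its fold enrichment was 1.49, where the lowest in that list was 1.33. PAX3 (chromosome 2, 222199887 to 222298998) was at 4.23 ± 1.54 and FOXO1 (chromosome 13, 40555667 to 40666641) at 2.96 ± 0.60 (SD, n = 3). The FOXO1 value leaves out summits that overlapped a second gene record, among them the replicate 3 peak with the highest −log10 q, in exon 2, with a fold enrichment of 5.27. The best PAX3 peak was intronic in replicates 1 and 2. The lysine methyltransferase genes EHMT1 and EHMT2, whose products methylate histone H3, were at 4.67 ± 1.23 and 4.16 ± 1.298 (SD, n = 3). With q under 1e-05 EHMT1 stayed in every list and EHMT2 did not. The best −log10 q of EHMT2 was 4.89, 2.86 and 12.9 in replicates 1, 2 and 3. PAX3 peaks that overlapped exons numbered 1, 1 and 6 in replicates 1, 2 and 3, so replicate 3 supplied most of them. All lay in exons 2 to 7 of the 9 exons of PAX3-206, with none in exons 1, 8 and 9. FOXO1 exonic peaks numbered 4, 1 and 7, all in exons 2 and 3, with none in exon 1. Exons 1 to 7 of PAX3 and 2 and 3 of FOXO1 are those kept in the fusion transcript. Counted here, but not in the gene assignment, were FOXO1 summits that overlapped a second gene record, 2 in replicate 1 and 3 in replicate 3. GC content was 55.9% in PAX3 exon 8, 38.9% in exon 9, 41.3% over both together and 67.1% in exon 1, against 50.8% to 65.7% in the exons with peaks. It was 74.03% in FOXO1 exon 1, against 36.5% and 50.4% in exons 3 and 2.

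**Figure D3:**
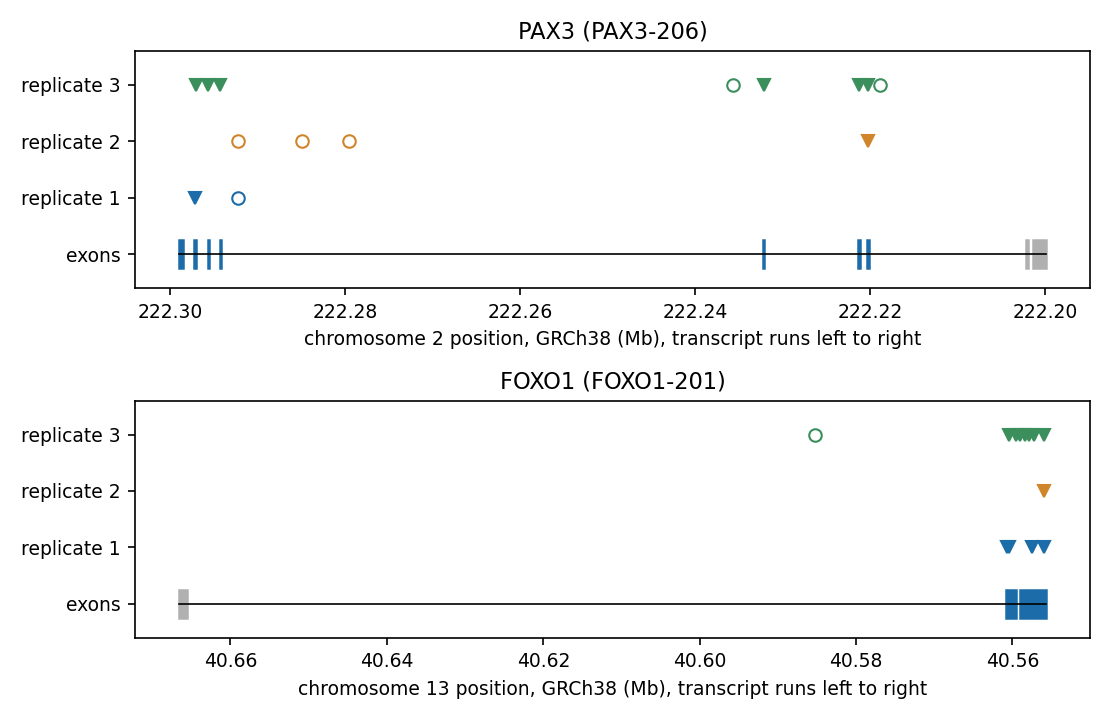
Peaks on PAX3 and FOXO1 (x axis, GRCh38 position in Mb, drawn in the direction of transcription) in replicates 1, 2 and 3 (y axis). Boxes are exons, blue where kept in the fusion transcript and grey where not, filled triangles are peaks that overlap an exon and open circles other peaks. No peak overlaps exons 8 and 9 of PAX3 or exon 1 of FOXO1.

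None of the gene list tests matched transcript abundance or exon length, so a pass cannot be read as preferential binding by DDX5. Of the 16 gene lists, 5 passed the threshold with more genes with a peak in every list than the background of 43.2%, and none passed it with fewer. Regulators of fusion-positive rhabdomyosarcoma had 26 such genes of 34 with any peak, an odds ratio of 4.28 (95% interval 1.94 to 9.46, Fisher's exact test, adjusted p = 0.0013). The growth factor gene IGF2 was at 4.82 ± 1.76, MEF2D at 7.26 ± 1.35 and PODXL at 8.08 ± 6.10 (fold enrichment, SD, n = 3). PODXL was at 2.67, 6.87 and 14.7 in replicates 1, 2 and 3. IGF2 held 2, 4 and 3 assigned peaks there, and 5, 4 and 5 further summits that overlapped a second gene record were left out. Microprocessor components and protein partners of DDX5 also had 26 of 34, an odds ratio of 4.28 (95% interval 1.94 to 9.46, exact test, adjusted p = 0.0013), among them the acetyltransferase genes CREBBP at 6.61 ± 1.44 and EP300 at 4.18 ± 1.01, the splicing regulator gene KHSRP at 3.87 ± 0.567 and the RNA-editing enzyme gene ADAR at 4.47 ± 1.92 (SD, n = 3). With fold enrichments of at least 4 neither of these lists passed (exact test, adjusted p = 0.059 and 1.0), and with q under 1e-05 the DDX5 partners did not (exact test, adjusted p = 0.052).

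Cell cycle and replication genes had 33 of 48, an odds ratio of 2.90 (95% interval 1.57 to 5.34, exact test, adjusted p = 0.0021), with the mitotic kinase gene PLK1 at 7.85 ± 2.78, the helicase gene MCM7 at 3.69 ± 1.47, CDC25B at 4.45 ± 2.18 and CHEK1 at 4.16 ± 0.706 (SD, n = 3). Genes of 12q13-q14, a region known to be amplified in RH30, had 21 of 28, an odds ratio of 3.95 (95% interval 1.68 to 9.29, exact test, adjusted p = 0.0035). GLI1, a hedgehog pathway transcription factor gene, was at 5.57 ± 0.932, LRP1 at 4.66 ± 0.473 and B4GALNT1 at 3.52 ± 0.601 (SD, n = 3), beside MBD6 above. LRP1 held 32 regions found in all lists. Lysine methyltransferases and heterochromatin factors had 26 of 40, an odds ratio of 2.44 (95% interval 1.27 to 4.68, exact test, adjusted p = 0.020), with KMT2D at 9.67 ± 1.79, KMT2A at 3.08 ± 0.196, SETD1A at 6.83 ± 0.961 and WIZ at 5.03 ± 0.794 (SD, n = 3). The methyltransferase call ended without replicate 1, 2 or 3 (exact test, adjusted p = 0.061, 0.25 and 0.072), with q under 1e-05 (0.052), with fold enrichments of at least 4 (0.072), without peaks on shared pairs of fold and p (0.21), for genes in 2 or more lists (0.46) and against random lists matched on length and gene type (permutation, 0.16). The 12q call ended without replicate 2 (exact test, adjusted p = 0.25), with q under 1e-05 (0.097), with fold enrichments of at least 4 (0.053) and for genes in 2 or more lists (0.073). The cell cycle call ended with q under 1e-05 (exact test, adjusted p = 0.34), with equal list lengths (0.056) and without peaks on shared pairs (0.27), and its odds ratio turned below 1 with fold enrichments of at least 4 (log2 odds ratio −0.39, exact test, adjusted p = 1.0).

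**Figure D4:**
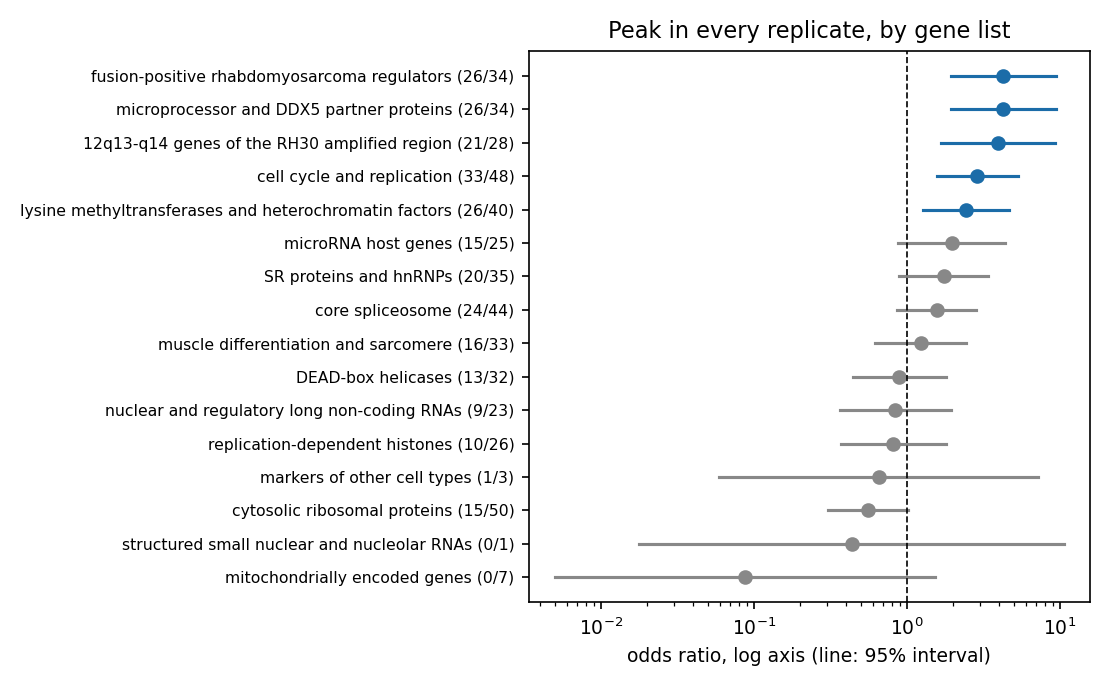
Odds ratio (x axis, log scale, lines are 95% intervals) of having a peak in every replicate for the members of each gene list (y axis), with the number in every list over the number with any peak. Blue lists passed an adjusted p of 0.05, and their odds ratios run from 2.44 to 4.28.

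The other 11 lists did not pass the test. Against all annotated genes of matched length and type, whether or not they had a peak, SR proteins and hnRNPs (20 against 9.28 expected), the core spliceosome (24 against 10.1), DEAD-box helicases and histones passed as higher (permutation, adjusted p = 0.0002, 0.0002, 0.027 and 0.0014). Annotated genes without a peak may not be expressed. Against matched genes with a peak none of these lists passed, with 14.5, 18.5, 13.7 and 9.31 expected (permutation, adjusted p = 0.16, 0.21, 0.92 and 0.92). Muscle differentiation and sarcomere genes had 16 of 33 (exact test, adjusted p = 0.87), with XIRP1 at 6.18 ± 1.36, TNNI1 at 3.54 ± 0.837, NEB at 3.51 ± 0.785 and BIN1 at 5.60 ± 0.451 (SD, n = 3). DEAD-box helicases had 13 of 32 (exact test, adjusted p = 0.98), with DDX23 at 4.92 ± 0.931, DDX24 at 3.77 ± 1.303, DDX54 at 4.85 ± 0.773 and DDX11 at 3.81 ± 0.761 (SD, n = 3). SR proteins and hnRNPs had 20 of 35 (exact test, adjusted p = 0.22), with SRRM2 at 3.36 ± 0.343 and PTBP1 at 4.92 ± 2.27, and the core spliceosome had 24 of 44 (exact test, adjusted p = 0.27), with PRPF8 at 5.76 ± 2.42 and SF3B3 at 5.65 ± 0.955 (SD, n = 3). MicroRNA host genes had 15 of 25 (exact test, adjusted p = 0.21), with CTDSP1 at 7.24 ± 0.0806, SREBF2 at 6.31 ± 1.81 and EVL at 7.56 ± 2.75 (SD, n = 3). Nuclear and regulatory long non-coding RNAs had 9 of 23 (exact test, adjusted p = 0.98), an odds ratio of 0.842, with NORAD at 2.79 ± 0.338, SNHG16 at 2.38 ± 0.068 and MEG8 at 3.34 ± 1.54 (SD, n = 3). Against random lists of genes with a peak matched on length and gene type, the microRNA host genes passed as higher, with 15 against 9.05 expected, and so did the long non-coding RNAs, with 9 against 3.87 expected (permutation, adjusted p = 0.030 and 0.020), so the direction of the latter list depends on the comparison genes. The microRNA host genes also passed as higher with fold enrichments of at least 4 and with exonic summits (exact test, adjusted p = 0.0078 and 0.040). Cytosolic ribosomal proteins had 15 of 50 (exact test, adjusted p = 0.14), with RPL3 at 2.15 ± 0.109 and RPL36 at 4.01 ± 1.74. This list passed as lower with q under 1e-05 and with exonic summits (exact test, adjusted p = 0.033 and 0.030). Its direction turned for genes in 2 or more lists (log2 odds ratio 0.17, exact test, adjusted p = 1.0) and against all annotated genes of matched length and type (15 against 9.27 expected, permutation, adjusted p = 0.055). Replication-dependent histones had 10 of 26 (exact test, adjusted p = 0.93), with H1-4 at 3.71 ± 1.55 (SD, n = 3). Mitochondrially encoded genes had 0 of 7 (exact test, adjusted p = 0.058), and all 7 had their assigned peaks in replicate 1 alone. This list passed as lower without replicate 2 or 3 (exact test, adjusted p = 0.0075 and 0.030), for genes in 2 or more lists (0.0033) and with exonic summits (0.047). As each of these rules needs a peak in a second list, 0 of 7 followed by construction. The passes repeat a single observation from replicate 1. Small nuclear and nucleolar RNAs had 0 of 1 (exact test, adjusted p = 1.0). Of 45 markers of other cell types, 3 had any peak and 1, the synaptotagmin gene SYT1 at 3.76 ± 1.42 (SD, n = 3), was in every list (exact test, adjusted p = 1.0). Against all annotated genes of matched length and type this list passed as lower, with 1 against 8.37 expected (permutation, adjusted p = 0.0049).

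The base composition under shared regions was compared with other places of the same genes. Windows were cut from the genome sequence, so they can cross an exon edge into an intron. The distance to an exon edge was not matched, so the differences below can reflect it. Over 7421 regions, GC content within 50 bases on each side of the summit was 50.5%, against 49.8% ± 0.103 (SD over 100 draws) at random places of the same gene and feature class, a difference of 0.683 points (permutation of positions, p = 0.0099, the smallest that 100 draws can give). Within 100 bases on each side the difference changed sign, to −0.422 points, and in the 1856 regions with the highest fold percentile it was 0.841 points (permutation of positions, p = 0.0099 for both). Windows able to form 4 runs of G were fewer on the gene strand, at 0.728% against 1.14% ± 0.132, and on the opposite strand, at 1.13% against 1.72% ± 0.139 (SD over 100 draws, permutation of positions, p = 0.0099 for both). Within 100 bases on each side they were also fewer, with differences of −1.22 and −1.26 points (permutation of positions, p = 0.0099 for both). In the regions with the highest fold percentile the differences were −0.281 points on the gene strand and −0.488 points on the opposite strand, and neither passed (permutation of positions, p = 0.39 and 0.24).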

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

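No test was run on the values in this part. Apart from the chromosome 21 values at the end, which belong to peaks that entered the results, they count peaks outside the main chromosomes. Those outside peaks enter no result except an alternative count of peaks. Replicates 1, 2 and 3 held 125, 51 and 79 peaks on such contigs. Of these, 22 in replicate 1 and 33 in replicate 3 lay on contigs that carry ribosomal DNA, where replicate 2 held 3. They are listed because a signal was present outside the main measurement. No control lists were analysed here to set a level. On chromosome 21, peaks also fell in the annotated ribosomal RNA copies, with a highest fold enrichment in RNA18SN3 of 18.04, 14.3 and 10.1 in replicates 1, 2 and 3, and reads from one copy cannot be assigned apart from those of another.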

How the results depend on the processing

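The alternatives of leaving out peaks on shared pairs of fold and p, and of giving a summit in several genes to the only protein-coding one, were chosen after the data were seen. The cause of each change below was not tested, except that stricter thresholds and left-out peaks leave fewer peaks and genes by construction. No paired analysis was possible because the INPUT samples have no list here and no group was compared with another. Library depth, which is unknown, limits how many peaks a list can hold. The exonic share stayed within 1 SD in 6 of 6 alternatives that kept all replicates, from 66.3% to 86.2%. Leaving out 1 of 3 replicates cannot move a mean by 1 SD, so its range of 71.3% to 82.4% says nothing of stability. The shared regions stayed above the shuffled number in 8 of 8. Single features moved by more than 1 SD with a fold of at least 4, to 9.49% intergenic, 4.26% non-coding exon and 2.03% 5' UTR, and without peaks on shared pairs, to 3.09% non-coding exon and 44.2% 3' UTR. With all contigs the mean number of peaks was 31151.

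With q under 1e-05 the mean number of peaks was 16247, shared regions 3446 and genes in every list 2550, with 2 lists called, 1 of them, the ribosomal proteins, as lower. The log2 odds ratio was then 1.26 for methyltransferases and 1.28 for DDX5 partners (exact test, adjusted p = 0.052 for both), 0.65 for the cell cycle (adjusted p = 0.34) and 1.21 for 12q (adjusted p = 0.097). Lists that had not been called turned sign, to −0.36 for muscle, 0.19 for DEAD-box helicases, −0.18 for SR proteins, −0.14 for the spliceosome and 0.22 for long non-coding RNAs. With a fold of at least 4 there were 5838 peaks, 490 shared regions, 686 genes, a mean rank correlation of 0.196 and 1 list called, the microRNA host genes. The log2 odds ratio was 1.62 for rhabdomyosarcoma regulators (exact test, adjusted p = 0.059), 1.59 for methyltransferases (0.072), 0.041 for DDX5 partners (1.0), 2.203 for 12q (0.053) and −0.39 for the cell cycle (1.0), and −0.10 for the spliceosome and 0.45 for other cell types. With equal list lengths it was 1.02 for the cell cycle (exact test, adjusted p = 0.056), 0.045 for long non-coding RNAs and 0.46 for other cell types.

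Without peaks on shared pairs of fold and p there were 11620 peaks, 3255 shared regions, 2184 genes, a mean rank correlation of 0.452 and 3 lists called. The log2 odds ratio was 0.86 for methyltransferases (exact test, adjusted p = 0.21), 0.64 for the cell cycle (0.27), −0.17 for the spliceosome, 1.18 for long non-coding RNAs, 0.31 for histones and 2.35 for other cell types. With exonic summits 8 lists were called, the ribosomal proteins and the mitochondrial genes as lower and 6 as higher, among them the microRNA host genes, with 0.44 for long non-coding RNAs and 0.44 for other cell types. In 2 or more lists there were 7105 genes, with 0.81 for methyltransferases (exact test, adjusted p = 0.46), 1.87 for 12q (0.073), 0.39 for DEAD-box helicases, 0.39 for small nuclear RNAs, 0.17 for ribosomal proteins and 0.54 for histones.

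Reciprocal overlap of 50% gave 4285 shared regions and summits within 100 bp gave 5041. Ranking by −log10 q gave a mean rank correlation of 0.43. Against genes with a peak of matched length and type, log2 observed over expected, with 0.5 added to both, was 0.35 for methyltransferases (permutation, adjusted p = 0.16), 1.12 for long non-coding RNAs and 0.10 for histones. Against all annotated genes of matched length and type 12 lists were called, 1 of them, the markers of other cell types, as lower. The value was 0.81 for DEAD-box helicases, 2.64 for long non-coding RNAs and 1.47 for histones, which were called, and 0.67 for ribosomal proteins, which were not (permutation, adjusted p = 0.055). The GC difference turned to −0.422 points within 100 bases on each side, and the G-run difference was −0.281 points in the 1856 regions of highest fold.

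With each replicate left out in turn, shared regions ranged from 9555 to 15811, genes in every remaining list from 4658 to 5698, lists called from 4 to 5 and the mean rank correlation from 0.323 to 0.44. The log2 odds ratio ranged from 0.90 to 1.28 for methyltransferases, 1.18 to 2.66 for 12q, −0.22 to 0.14 for DEAD-box helicases, −2.22 to 1.18 for small nuclear RNAs, −0.27 to 0.80 for muscle, −1.09 to 1.105 for histones and −1.41 to 0.37 for other cell types. Across all alternatives, the adjusted p ranged from 0.0002 to 0.059 for rhabdomyosarcoma regulators, 0.00012 to 1.0 for DDX5 partners, 0.0002 to 1.0 for the cell cycle, 0.0002 to 0.25 for 12q and 0.00036 to 0.46 for methyltransferases, by exact or random-list permutation tests. Of 555 values of named genes under the alternatives, 17 moved by more than their spread between replicates, which leaving out a replicate could not do. A stricter q and equal list lengths also keep a gene's best peak in a list whenever they keep any of its peaks there. Many of the 555 values could therefore hardly move, and the number says little of stability.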

Other observations

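The tests of genomic DNA, shared value pairs, abundance, placement and GC content in this part were chosen after the result was seen. The genes named in this and the next paragraph, except LRP1, lie outside the naming rule and were chosen after their values were seen. Among nuclear RNAs, MALAT1 held 0 peaks in every list, and H19 held 0. As no INPUT level was analysed, 0 peaks does not show that a transcript was unbound. NEAT1 held 13, 5 and 0 peaks in replicates 1, 2 and 3, KCNQ1OT1 held 5, 11 and 14, and MEG3 held 8, 4 and 4. Summits left out because they overlapped a second gene record numbered 1 each for NEAT1 and MEG3 in replicate 2. RN7SK held 1 summit in each list that overlapped a second gene record and was left out of the assignment. Of the myogenic and fusion target genes, MYOD1 was at a best fold enrichment of 2.11 ± 0.525, MYOG at 2.92 ± 0.769, MYCN at 3.17 ± 1.31 and FGFR4 at 3.79 ± 1.32 (SD, n = 3), each with a peak in every list. DROSHA, the nuclease of the microprocessor, was at 4.18 ± 1.04 (SD, n = 3), and its partner DGCR8 had peaks in replicates 1 and 3 and 1 left-out summit in replicate 2. The paralogue DDX17 was at 2.51 ± 0.331 (SD, n = 3).

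Some genes held many shared regions, counted here without regard to transcript length. HUWE1, a ubiquitin ligase gene, held 33 regions found in all lists, LRP1 held 32, NAV1 held 27 and DYNC1H1 and UBR4 held 25 each. COPG2 held 12 intronic regions found in all lists. Across 4277 protein-coding genes with a peak in every list, exonic GC content correlated with the best fold enrichment with Spearman's rho of 0.25, 0.15 and 0.33 in replicates 1, 2 and 3. Genes are not independent replicates.

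Replicate 2 had a higher share of intronic peaks, 32.7%, than replicates 1 and 3, with 11.9% and 16.3%. It held 7732 intronic and 14647 exonic peaks, where replicate 1 held 2814 and 19981 and replicate 3 held 7476 and 36939, so against replicate 3 the share differed through fewer exonic peaks. If genomic DNA added intergenic peaks about as densely per Mb as intronic ones, both excesses would be about alike. The intergenic excess over replicate 1 was 0.0886 of the intronic one (95% interval 0.0655 to 0.112 from Poisson resampling, for counting error only). At equal numbers of exonic peaks it was 0.130 against replicate 1 and 0.184 against replicate 3 (0.164 to 0.205). These values argue against evenly added DNA peaks as the whole cause, as far as single libraries can tell. Peaks and not reads were counted, so DNA that added peaks unevenly is not covered. Peaks that share their pair of fold and p were not the whole cause of the higher intronic share, as that share among the other peaks was 1.99 times that of the nearer replicate. Unspliced RNA or a lower detection of exonic peaks may account for it, which the lists cannot test, and no biological explanation was tested because all 3 lists belong to one group.

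Genes of 12q13-q14 were more often in every list than other genes. Gene span, introns included, does not account for it, with an adjusted p of 0.0032 (permutation) against lists matched on span and gene type. Exon length was not matched, so it stays open. Peaks on shared pairs of fold and p do not account for it either, with an adjusted p of 0.0052 (exact test) without them. A candidate explanation is that amplified genes give abundant transcripts, whose peaks reach significance at a low fold. The 21 genes had a mean fold percentile 12.4 points below that of the 4395 other genes in every list (difference −12.4, permutation p = 0.0083), and a −log10 q percentile 7.09 points above (p = 0.081). As the second difference did not pass, abundance stays open. The genomic DNA comparison above covered all main chromosomes together, so it says nothing of DNA from this region. The call itself ended without replicate 2 (log2 odds ratio 1.18, exact test, adjusted p = 0.25), the highest adjusted p of the alternatives, the lowest being 0.0002, and no biological explanation was tested.

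Exonic peaks of PAX3 and FOXO1 lay in the exons kept in PAX3-FOXO1, and one hypothesis is that they come from the fusion transcript. After merging, PAX3 had 6 distinct exonic regions and FOXO1 8, and replicate 3 held 6 of the 8 PAX3 exonic peaks and 7 of the 12 of FOXO1. Of 327 other genes with 6 regions, 3.67% (exact 95% interval 1.91 to 6.32) lacked one in the same last part of the transcript, and 6.52% did on average when genes with more regions were thinned to 6, which leaves a placement common to other genes open for PAX3. For FOXO1, 21.03% of 233 genes with 8 regions (15.98 to 26.8) lacked one in the same first part, so such placement can account for it. GC content also stays open for both, as the exons left out of the fusion, when pooled, lay outside the range of those with peaks, at 41.3% in PAX3 and 74.03% in FOXO1. Exon 1 of PAX3, kept in the fusion, also held no peak and lay outside that range, at 67.1%. Against GC content for PAX3, exon 8 held no peak at 55.9%, inside the range. FOXO1 exon 3 held 8 peaks at 36.5%, so a low GC content alone did not prevent peaks in these lists.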
